A study of Mus musculus with 17 samples.

How the data were processed

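The data were bulk RNA sequencing of 16 lung samples, 4 in each of 4 groups, and 1 sample of the injected cell product. Per the labels, total RNA from flash frozen lung was prepared with TRIzol and standard Illumina protocols. The submitters' processing notes name STAR 2.7.3a, Partek and the mouse genome build mm10, without an annotation or settings. The values deposited by the authors are FPKM for 18262 genes in 17 library columns. FPKM times the genomic span of the gene (introns included, as listed with each gene) divided by 1000 summed to 1000000 in every column, so the length used is the span and the value times its length is reads per 1000000 assigned reads (RPM). The smallest step of these values gave the read number of each library, 27566840 to 36815044 in lungs and 31111308 in the product. On that step 86.7 to 88.4% of values under 1000 reads were whole within 0.02, and the rest are fractional for a reason that is not stated. FPKM per genomic span is low for genes with long introns. No mitochondrial gene is listed, so the mitochondrial list had 0 members. All 16 lung libraries had Ddx3y above Xist, and no replicates were duplicates of each other.

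Lung values were analysed as log2(FPKM + 0.5) for 10284 genes with at least 0.5 FPKM in at least 4 lung libraries. limma 3.58.1 in R 4.3.3 fitted the 4 group means over the 16 lungs, with trend and robust moderation and 2-sided tests, and p values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. The comparisons were 5 pairs of groups and the interaction of tumor and GEMy. Fold changes include the added 0.5 and understate changes of genes near or below it. Il12a, Il12b and Foxp3 lay under the minimum, so they are given from a limma fit on log2(RPM + 0.5) over 14685 genes, a fit chosen after the values were seen. Means and SD are of FPKM over 4 libraries. Where a group had 0 reads, a fold is a lower bound against a floor of 3 reads over its 4 libraries. Counting intervals are exact 95% Poisson intervals for 1 library and exact conditional intervals for a ratio, and floors and intervals cover counting error only.

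Before the data were examined, 31 gene lists of immune, lung cell, pathway and possible contaminant genes were fixed with the groups, comparisons, gene rule and most alternatives. The 27 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists, with camera on an estimated correlation and fry beside it. Lists overlap, since interferon genes belong to more than 1, and bulk lung cannot assign a transcript to a cell type. The genes named were, for each of the comparisons with untreated lungs of the same tumor status and of tumor_untreated with naive_untreated, the 6 largest rises and 4 largest falls past the threshold whose groups did not overlap. To these were added the 2 most changed members of each called list, the 5 largest interaction values on each side, and 10 fixed genes in every comparison. The value of 1 list member picked by this rule is not reported here. For the product the 10 most abundant and the 10 most abundant enriched genes were used, with enriched meaning at least 10 FPKM and at least 8 times the lung mean. Predicted gene models, pseudogenes, histone, ribosomal protein, receptor segment and small RNA genes were left out of the ranked picks. H2-Ob, Il10 and Lgals9 in comparisons where the rule did not pick them, Il12rb1, the fall of Ebi3, and other genes given for a comparison that did not pick them were chosen after their values were seen, as was Gzme.

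Alternatives were a pseudocount of 0.1 or 1, no minimum or a minimum of 1 FPKM, median-of-ratios scaling, quantile normalization, plain moderation, only the compared groups in the fit, the replicate number as a block, array weights, a 2-fold minimum, leaving out each library, and product enrichment of at least 4 times. Alternatives chosen after seeing the data were RPM, voom on recovered reads, correction for the GC content of transcripts, hemoglobin as a covariate, and overlaps of effects with the shared untreated group split 2 and 2. Correlations between effects were compared with 20 simulations of unchanged groups. The method was tested on simulated data made from these libraries, where 80 to 83% of planted 1.5-fold and 94 to 95% of planted 2-fold changes were called, with 2 to 12 false calls in 10164 to 10211 genes tested. A list with a planted 1.3-fold change was called, with 0 others. Simulated genes varied independently of each other, with 1 spread per gene for all groups. Lists of correlated genes and groups of unequal spread were therefore not tested. Other splits of the libraries were counted as in the closing section. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. The sequence of the IL-12 construct and raw reads were not analysed here.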

Results

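The data were RNA sequencing profiles of lungs from C57BL/6 mice, 4 libraries in each of 4 groups, and 1 library of the injected cell product. Mice were naive or carried M3-9-M tumors, a mouse rhabdomyosarcoma line with firefly luciferase and mCherry, started from 500000 cells in the gastrocnemius muscle. They were left untreated or received 8000000 IL12-GEMy cells intravenously, and lungs were taken 3 days after treatment. In tumor-bearing mice the cells were given on day 12 and lungs taken on day 15 after tumor inoculation. IL12-GEMy cells are bone marrow derived myeloid cells transduced to secrete interleukin-12 (IL-12), a cytokine that drives interferon-gamma production by T cells and natural killer cells. The groups are called naive_untreated, naive_GEMy, tumor_untreated and tumor_GEMy. The title of the study concerns the lung pre-metastatic niche, the state of a tissue before tumor cells settle there. The recovered depth was 27566840 to 36815044 assigned reads per lung library and 31111308 for the cell product. Values in FPKM times gene length are reads per 1000000 (RPM), and gene positions are on mm10. Titles number the samples, and whether the 4 libraries of a group came from separate mice is not stated. The adjusted p values measure the spread between these libraries. Descriptions of the tumor-bearing samples also carry the number 1 in all 4 untreated and 2 in all 4 treated samples, and whatever that number stands for could not be separated from treatment.

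The first principal component held 53.8% of the variance of the 16 lung libraries and placed the naive_untreated libraries lowest, with tumor_untreated libraries spread from 5.70 to 31.2. The second held 18.6% and separated lungs with IL12-GEMy from those without. Pearson correlations between replicates on the log2 scale were 0.973 to 0.997.

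**Figure D1:**
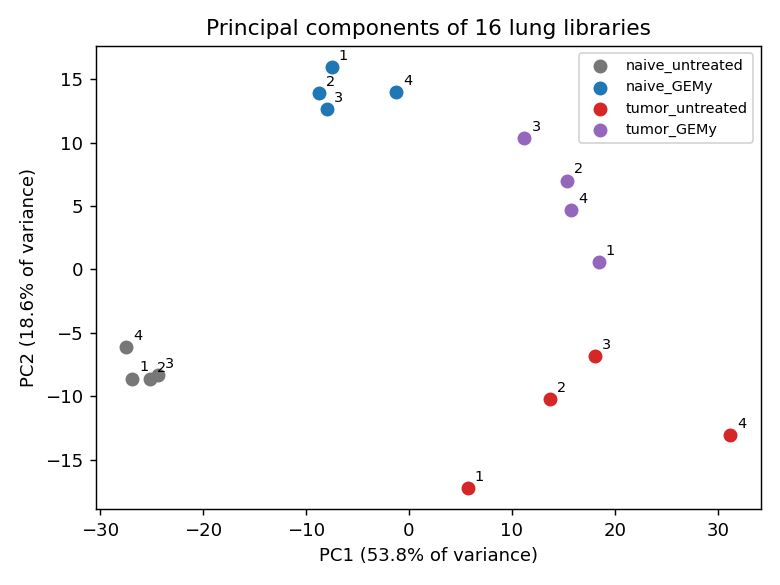
Scores of the 16 lung libraries on the first and second principal component of log2(FPKM + 0.5), coloured by group and numbered by replicate. The components hold 53.8% and 18.6% of the variance, and the 4 groups occupy separate areas, with the widest spread among the tumor_untreated libraries.

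Comparing tumor_untreated with naive_untreated asked how a distant tumor changed the lung. Neutrophil genes had some of the largest rises. S100a8 (chromosome 3, 90669071 to 90670034), which encodes a calcium-binding protein abundant in neutrophils, went from 38.0 ± 8.51 to 914 ± 259 FPKM (SD, n = 4; log2 fold change 4.56, SE 0.32, adjusted p = 7.05e-08). S100a9 (log2 4.48) and Retnlg (4.49) rose by similar amounts. The interferon-induced chemokine genes Cxcl10 (0.601 ± 0.0594 to 23.5 ± 14.9 FPKM, log2 4.18) and Cxcl9 (0.112 ± 0.0140 to 13.0 ± 9.38 FPKM, log2 4.14) also rose. The ranked genes were picked only among those that separated all 4 libraries of one group from all 4 of the other. Several granzyme genes of cytotoxic lymphocytes were at or near 0 in naive lungs. Gzmg (chromosome 14, 56156581 to 56159579) had 0 reads over the 4 naive_untreated libraries and 7006 in tumor_untreated, at least 2174-fold higher against a floor of 3 reads over the group. Gzmd rose at least 1957-fold and Gzmf at least 2354-fold on the same floor, and Gzme went from 1 to 2674 reads (ratio 2489, 95% counting interval 446 to 98365). Replicate 4 of tumor_untreated held 3637 of the Gzmg reads, and without it the folds were at least 1416 for Gzmg, 1288 for Gzmd and 1528 for Gzmf, and the Gzme ratio was 1691 (303 to 66838). Gzmc to Gzmg are neighbouring paralogs, so the division of reads among them is uncertain. The largest falls were Ankrd63 (log2 -1.53, adjusted p = 1.23e-06), the xenobiotic enzyme gene Cyp1a1 (-1.29), the B cell gene Fcer2a (-1.17) and Tril (-1.14).

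Among the lists of immune genes, the neutrophil list had the largest shift: 17 of 17 tested members rose (17 adjusted over the list alone), with a median log2 fold change of 2.86 and a camera adjusted p = 1.28e-19, or adjusted p = 0.148 with an estimated correlation. Of the interferon-gamma response list, 26 of 26 tested members rose (26 adjusted over the list alone), with a median log2 fold change of 1.76 and a camera adjusted p = 7.00e-19, or adjusted p = 0.157 with an estimated correlation. Of the type I interferon list, 22 of 22 tested members rose (22 adjusted over the list alone; median 1.01, camera adjusted p = 6.55e-15, adjusted p = 0.157 with an estimated correlation). Rsad2 (log2 2.62) and Zbp1 (2.45) moved most. For MHC class I presentation, 18 of 19 tested members rose (19 adjusted over the list alone; median 0.88, camera adjusted p = 5.84e-14, adjusted p = 0.157 with an estimated correlation). Tap1 changed by a log2 of 1.49. Monocyte and macrophage markers moved the same way, as 16 of 18 tested members rose and 1 fell (16 rising and 1 falling adjusted over the list alone; median 0.97, camera adjusted p = 2.47e-11, adjusted p = 0.148 with an estimated correlation), and Fcgr4 (2.43) and Ly6c2 (2.24) led them. For cytotoxic and NK cell markers, 15 of 15 tested members rose (15 adjusted over the list alone; median 0.87, camera adjusted p = 8.56e-09, adjusted p = 0.192 with an estimated correlation). Gzmb changed by a log2 of 3.02 and Prf1 by 1.68. The myeloid immune suppression list was the 1 call of 22 that held with an estimated correlation: 14 of 20 tested members rose and 2 fell (15 rising and 4 falling adjusted over the list alone; median 0.72, camera adjusted p = 4.18e-07, adjusted p = 0.0447 with an estimated correlation). In it, the arginase gene Arg1 (chromosome 10, 24915207 to 24927470) went from 0.186 ± 0.0110 to 1.24 ± 0.684 FPKM (log2 1.25, adjusted p = 0.000116), Trem1 rose by 2.62 and Cd33 by 2.16. Cd274, the gene of the checkpoint ligand PD-L1 (chromosome 19, 29367438 to 29388094), rose from 1.59 ± 0.173 to 8.15 ± 4.56 FPKM (log2 fold change 1.88, SE 0.28, adjusted p = 9.00e-05). Ifng rose from 0.0444 ± 0.0136 to 0.602 ± 0.426 FPKM (log2 0.94, adjusted p = 0.00166), a call lost after quantile normalization (adjusted p = 0.0508).

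Smaller immune lists also shifted. MHC class II genes were mixed, as 9 of 13 tested members rose and 3 fell (9 rising and 3 falling adjusted over the list alone; median 0.37, camera adjusted p = 0.00491, adjusted p = 0.399 with an estimated correlation), with Ctss and Ifi30 up and H2-Ob (-0.62) down. In the IL-12 and T helper 1 list, 5 of 6 tested members rose (5 rising and 1 falling adjusted over the list alone; median 0.78, camera adjusted p = 0.000675, adjusted p = 0.148 with an estimated correlation). Granule genes of immature myeloid cells gave 5 rises and 1 fall among 11 (7 and 1 adjusted over the list alone; median 0.77, camera adjusted p = 0.00869, adjusted p = 0.274 with an estimated correlation). Ctsg changed by a log2 of 1.66. Of the dendritic cell list, 4 of 7 tested members rose and 1 fell (4 rising and 1 falling adjusted over the list alone; median 0.22, camera adjusted p = 0.0116, adjusted p = 0.211 with an estimated correlation). Of chemokine and cytokine genes, 8 of 16 tested members rose and 1 fell (8 rising and 1 falling adjusted over the list alone; median 0.55, camera adjusted p = 0.000135, adjusted p = 0.157 with an estimated correlation). Ccl4 (log2 2.30) and Ccl3 (2.11) moved most. In the matrix remodelling and pre-metastatic niche list, 8 of 16 tested members rose and 3 fell (8 rising and 4 falling adjusted over the list alone; median 0.37, camera adjusted p = 0.00586, adjusted p = 0.148 with an estimated correlation). Ccl2 changed by a log2 of 1.56. Proliferation genes were up, as 14 of 15 tested members rose (15 adjusted over the list alone; median 0.46, camera adjusted p = 3.67e-08, adjusted p = 0.184 with an estimated correlation). Ube2c changed by a log2 of 1.25 and Mki67 by 0.87. For immediate early and heat shock genes, 9 of 14 tested members rose and 1 fell (10 rising and 1 falling adjusted over the list alone; median 0.64, camera adjusted p = 3.55e-05, adjusted p = 0.157 with an estimated correlation). Hspa1a changed by a log2 of 1.86. Of T cell markers, 7 of 12 tested members rose (7 rising and 1 falling adjusted over the list alone; median 0.33, camera adjusted p = 0.00944, adjusted p = 0.40 with an estimated correlation). Cd8a changed by a log2 of 0.89. The camera call was lost without tumor_untreated replicate 4 (adjusted p = 0.0575). Erythroid and platelet markers had 2 rises among 13 (2 adjusted over the list alone; median 0.97, camera adjusted p = 0.00862, adjusted p = 0.455 with an estimated correlation), also lost without tumor_untreated replicate 4 (adjusted p = 0.0602). Hemoglobin transcripts took 0.553 to 5.41% of reads in tumor_untreated and 0.190 to 1.51% in naive_untreated, with 5.41% in tumor_untreated replicate 4.

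Lists of resident lung cells and B cells fell. For airway epithelial markers, 12 of 12 tested members fell (12 adjusted over the list alone; median -0.44, camera adjusted p = 0.000669, adjusted p = 0.211 with an estimated correlation). Bpifb1 changed by a log2 of -0.82. Bpifa1 (-0.80, adjusted p = 0.0391) and the alveolar gene Ager (-0.73, adjusted p = 0.0452) fell too, but both lost their calls with no minimum (adjusted p = 0.0582 and 0.0667), median-of-ratios scaling (0.0517 and 0.0607), hemoglobin as a covariate (0.190 and 0.222) and a fit of the 8 compared libraries alone (0.0884 and 0.0699). Bpifa1 also lost its call with array weights (-0.23, adjusted p = 0.458), and Ager with voom (0.0504). Leaving out any 1 of naive_untreated replicates 1, 3 and 4 or tumor_untreated replicates 3 and 4 did the same for Bpifa1 (adjusted p = 0.0644 to 0.145), as did any 1 of naive_untreated replicates 1 to 4 or tumor_untreated replicate 4 for Ager (0.0536 to 0.154). For alveolar epithelial markers, 11 of 17 tested members fell (13 adjusted over the list alone; median -0.50, camera adjusted p = 0.000230, adjusted p = 0.177 with an estimated correlation). Among these Akap5 fell by 0.81 (adjusted p = 0.0217). That call was lost without naive_untreated replicate 3 (adjusted p = 0.0615) or tumor_untreated replicate 4 (adjusted p = 0.0616) and with hemoglobin as a covariate (adjusted p = 0.165). Of the fibroblast and smooth muscle list, 9 of 14 tested members fell (9 adjusted over the list alone; median -0.40, camera adjusted p = 0.00203, adjusted p = 0.307 with an estimated correlation). Mfap4 changed by a log2 of -0.83. Of the B cell and plasma cell list, 7 of 10 tested members fell (7 adjusted over the list alone; median -0.71, camera adjusted p = 0.000485, adjusted p = 0.222 with an estimated correlation). Cd79b changed by a log2 of -1.03. Cardiac muscle markers fell in 9 of 11 (10 adjusted over the list alone; median -0.53, camera adjusted p = 0.00471, adjusted p = 0.40 with an estimated correlation). Sln changed by a log2 of -0.64. No call was made for endothelial markers (1 rose and 6 fell of 14, camera adjusted p = 0.233), regulatory T cell and checkpoint genes (3 rose of 5, 0.125, and 7.12e-06 on RPM with 13 members tested), alveolar macrophage markers (0.706), circadian clock genes (0.433), or adipocyte and mesothelial markers (0.0558, and 0.0325 without naive_untreated replicate 1). With fry the T cell (adjusted p = 0.0579) and erythroid calls (0.128) were lost, and the regulatory T cell (0.00983), endothelial (0.0378) and adipocyte lists (0.00230) were called. In lists too small to test, both tested mast cell, basophil and eosinophil genes rose, both tested myogenic genes fell, and the 1 thymocyte gene did not pass. On RPM, Il12a fell by 0.76 on the log2 scale (adjusted p = 0.00130), Il12b rose by 1.47 (adjusted p = 5.80e-05), and Foxp3 did not pass at 0.32 (adjusted p = 0.208).

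In all, 4530 of 10284 tested genes changed at an adjusted p under the threshold in limma, 1733 higher and 2797 lower, and 336 rose and 10 fell at least 2-fold. After median-of-ratios scaling the split was 2191 higher and 2059 lower, the only setting without an excess of lower genes apart from the 2-fold minimum. Among the others the split was 1690 and 3149 after quantile normalization, 2239 and 3971 on RPM and 1456 and 1653 with hemoglobin as a covariate.

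Comparing tumor_GEMy with tumor_untreated asked what the cells changed in lungs already exposed to a tumor. Cd274 rose from 8.15 ± 4.56 to 28.4 ± 3.62 FPKM (SD, n = 4; log2 fold change 1.90, SE 0.28, adjusted p = 0.000688). Arg1, whose product depletes arginine and restrains T cells, fell from 1.24 ± 0.684 to 0.225 ± 0.0658 FPKM (log2 fold change -1.18, SE 0.19, adjusted p = 0.00140). The interferon-inducible GTPase genes Gbp10 (log2 2.43), Tgtp1 (2.11) and Iigp1 (2.04) and the serpin gene Serpina3f (2.18) were among the 6 largest rises. The other 2 were Clca1 and Retnla. Clca1 went from 0.698 ± 0.595 to 14.5 ± 13.1 FPKM (log2 fold change 3.22, SE 0.57, adjusted p = 0.00344). Retnla (chromosome 16, 48842609 to 48844461) went from 25.1 ± 6.12 to 144 ± 81.2 FPKM (log2 fold change 2.34, SE 0.31, adjusted p = 0.000302). The 4 largest falls were granzyme genes: Gzmg fell from 18.8 ± 13.2 to 3.44 ± 1.05 FPKM (log2 fold change -2.09, SE 0.32, adjusted p = 0.00112), Gzmd by 1.98, Gzmf by 1.96 and Gzmc by 1.74. The granzyme genes did not move alike, since Gzma rose (log2 0.95, adjusted p = 0.0394). That call was lost without tumor_untreated replicate 1 or 3 or tumor_GEMy replicate 2 or 3 (adjusted p = 0.0709 to 0.114). It was also lost with no minimum (adjusted p = 0.0688), with hemoglobin as a covariate (adjusted p = 0.0581) and in a fit of the 8 compared libraries alone (adjusted p = 0.141). Gzmb did not pass (-0.27, adjusted p = 0.632) but fell without tumor_untreated replicate 1 (-0.64, adjusted p = 0.00891). Ifng rose from 0.602 ± 0.426 to 1.76 ± 0.444 FPKM (log2 1.09, adjusted p = 0.00347). Cxcl9 did not pass (log2 0.059, adjusted p = 0.963). S100a8 (log2 -0.84, adjusted p = 0.142) and S100a9 (-0.80, 0.125) did not pass either, but both passed without tumor_GEMy replicate 1, at -1.19 (adjusted p = 0.00801) and -1.15 (adjusted p = 0.00428). Array weights also gave a call for S100a8 (adjusted p = 0.0499) and S100a9 (adjusted p = 0.0415). On RPM, Il12a (-0.16, adjusted p = 0.654), Il12b (0.19, adjusted p = 0.706) and Foxp3 (0.12, adjusted p = 0.821) did not pass.

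Of the interferon-gamma response list, 21 of 26 tested members rose (21 adjusted over the list alone), with a median log2 fold change of 1.40 and a camera adjusted p = 5.74e-30, or adjusted p = 0.156 with an estimated correlation. For MHC class I presentation, 17 of 19 tested members rose (19 adjusted over the list alone; median 0.67, camera adjusted p = 5.02e-25, adjusted p = 0.156 with an estimated correlation). For type I interferon genes, 13 of 22 tested members rose (16 adjusted over the list alone; median 0.61, camera adjusted p = 2.51e-16, adjusted p = 0.156 with an estimated correlation). Ifit3b changed by a log2 of 1.31. Of MHC class II genes, 7 of 13 tested members rose (7 adjusted over the list alone; median 0.43, camera adjusted p = 1.06e-07, adjusted p = 0.189 with an estimated correlation), led by their transactivator Ciita (1.26). Proliferation genes rose further, as 10 of 15 tested members rose (13 adjusted over the list alone; median 0.39, camera adjusted p = 6.09e-13, adjusted p = 0.156 with an estimated correlation). Top2a changed by a log2 of 0.65 and Mki67 by 0.59. The neutrophil list moved down: 7 of 17 tested members fell (10 adjusted over the list alone), with a median log2 fold change of -0.75 and a camera adjusted p = 2.00e-09, or adjusted p = 0.189 with an estimated correlation, led by Il1b (-1.42) and Clec4e (-1.27). The mean level of the list, as log2 above naive_untreated, was 3.02 in tumor_GEMy replicate 1, within the 2.66 to 3.27 of tumor_untreated, and 1.70 to 2.07 in the other 3 treated libraries. Immediate early and heat shock genes also moved down, as 4 of 14 tested members fell (6 adjusted over the list alone; median -0.60, camera adjusted p = 3.89e-06, adjusted p = 0.156 with an estimated correlation). Nr4a1 (log2 -1.58) and Dusp1 (-0.82) moved most. On the same scale that list was at 0.635 to 0.896 in tumor_untreated and at most 0.452 in any other lung library. In the IL-12 and T helper 1 list, 3 of 6 rose, Ifng, Tbx21 (0.81) and Il12rb1 (0.55), and Ebi3 fell (3 rising and 1 falling adjusted over the list alone; median 0.32, camera adjusted p = 0.00620, adjusted p = 0.156 with an estimated correlation). Of chemokine and cytokine genes, 6 of 16 tested members rose and 1 fell (7 rising and 1 falling adjusted over the list alone; median 0.14, camera adjusted p = 0.000641, adjusted p = 0.189 with an estimated correlation). Ccl8 changed by a log2 of 1.07 and Ccl19 by 1.00.

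Of cytotoxic and NK cell markers, 5 of 15 tested members rose (7 adjusted over the list alone; median 0.24, camera adjusted p = 0.000199, adjusted p = 0.516 with an estimated correlation). Xcl1 changed by a log2 of 1.07. The camera call was lost without tumor_untreated replicate 1 (adjusted p = 0.116). Alveolar epithelial markers moved up with few members passing, as 1 of 17 tested members rose (2 adjusted over the list alone; median 0.22, camera adjusted p = 3.20e-05, adjusted p = 0.156 with an estimated correlation). Of airway epithelial markers, 2 of 12 tested members rose (3 adjusted over the list alone; median 0.061, camera adjusted p = 0.0117, adjusted p = 0.491 with an estimated correlation). Muc5b changed by a log2 of 0.80. The list call was lost without tumor_untreated replicate 3 (adjusted p = 0.131). Of adipocyte and mesothelial markers, 1 of 5 tested members rose (3 adjusted over the list alone; median 0.26, camera adjusted p = 0.000641, adjusted p = 0.156 with an estimated correlation). Of alveolar macrophage markers, 1 of 10 tested members rose (2 adjusted over the list alone; median 0.15, camera adjusted p = 0.0128, adjusted p = 0.517 with an estimated correlation). That call was lost without tumor_untreated replicate 1 (adjusted p = 0.0544), tumor_untreated replicate 2 (adjusted p = 0.0990) or tumor_GEMy replicate 4 (adjusted p = 0.188). The myeloid immune suppression list was split, as 3 of 20 tested members rose and 6 fell (3 rising and 7 falling adjusted over the list alone; camera adjusted p = 0.547), with Il10 (0.94) and Lgals9 up and Trem1 (-0.96) and Cd33 (-0.71) down. Monocyte and macrophage markers gave 3 rises and 2 falls (camera adjusted p = 0.801, and 0.0364, downward, without tumor_untreated replicate 1). With fry the calls of the cytotoxic (adjusted p = 0.213), airway (0.213) and alveolar macrophage lists (0.268) were lost. In limma 0 T cell, B cell, endothelial and fibroblast markers passed, also on RPM, and 3, 1, 1 and 3 of them had an unadjusted p under 0.05. The T cell list was called upward without tumor_untreated replicate 4 (camera adjusted p = 0.0122) and the fibroblast list without tumor_GEMy replicate 2 (0.0478). The cardiac muscle list was not called (camera adjusted p = 0.0631), but was called upward on RPM (0.0435) and without tumor_untreated or tumor_GEMy replicate 1 or 2 (0.000350 to 0.0424). The erythroid and platelet list was not called either (camera adjusted p = 0.404), but was called downward without tumor_untreated replicate 3 (0.0152) or tumor_GEMy replicate 1 (0.00277).

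Between tumor_GEMy and tumor_untreated 692 genes changed in limma, 309 higher and 383 lower, 50 and 18 of them at least 2-fold. The balance turned in other settings, with 362 higher and 337 lower after quantile normalization and 307 and 261 without tumor_untreated replicate 3, and array weights gave 694 and 1664. Leaving out tumor_GEMy replicate 2 gave 452 genes, 228 higher and 224 lower, and a fit on the 8 compared libraries alone gave 210, 124 higher and 86 lower. That smaller fit lost the calls of 13 named genes, among them Ifng (adjusted p = 0.0653), Arg1 (adjusted p = 0.0539), Clca1 (adjusted p = 0.0559), Gzmf (adjusted p = 0.0525), Gzmc (adjusted p = 0.0554), Mki67 (adjusted p = 0.0760), Muc5b (adjusted p = 0.0630) and Dusp1 (adjusted p = 0.0646).

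**Figure D2:**
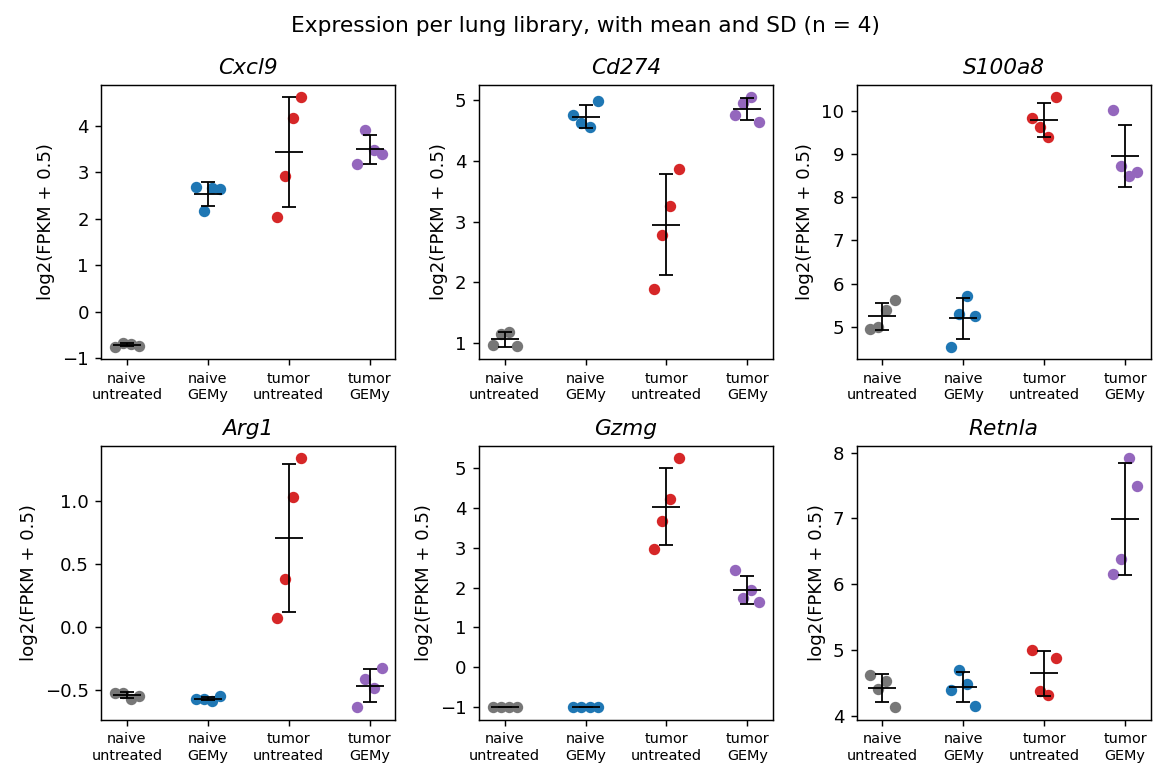
Expression of 6 named genes as log2(FPKM + 0.5) in each lung library by group, with points for libraries and bars for the mean and SD of 4 libraries. S100a8 is high in both tumor groups alone, Cd274 is highest after GEMy, and Arg1 and Gzmg are high in tumor_untreated and lower in tumor_GEMy.

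Comparing naive_GEMy with naive_untreated asked what the cells did without a tumor. Interferon-inducible genes had the largest rises. Serpina3f (chromosome 12, 104214544 to 104221129) went from 0.485 ± 0.106 to 23.9 ± 7.87 FPKM (SD, n = 4; log2 fold change 4.58, SE 0.24, adjusted p = 9.01e-09). The GTPase genes Tgtp1 (4.40), Igtp (3.96), Gbp6 (3.78) and Gbp10 (3.77), which act against intracellular pathogens, rose with Cxcl10 (4.04). Cxcl9 rose from 0.112 ± 0.0140 to 5.35 ± 0.929 FPKM (log2 3.24, adjusted p = 4.10e-05) and Cd274 from 1.59 ± 0.173 to 26.2 ± 3.60 FPKM (log2 3.67, adjusted p = 2.52e-07). Ifng rose from 0.0444 ± 0.0136 to 0.755 ± 0.148 FPKM (log2 fold change 1.20, SE 0.20, adjusted p = 0.000959). The largest falls were Nptx1 (-1.08), the endothelial genes Aplnr (-0.79) and Esm1 (-0.69), and Ankrd63 (-0.69). S100a8 (log2 -0.048, adjusted p = 0.953), S100a9 (-0.13, 0.857) and Arg1 (-0.027, 0.956) did not pass. On RPM Il12b rose by 1.06 (adjusted p = 0.00446), whereas Il12a (-0.53, adjusted p = 0.0516) and Foxp3 (-0.21, adjusted p = 0.588) did not pass. Mki67 rose by 0.54 (adjusted p = 0.0147). That call was lost without naive_untreated replicate 4 (adjusted p = 0.0516) or naive_GEMy replicate 3 (adjusted p = 0.0507).

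Of the 18 lists called here, 8 held with an estimated correlation. Of the interferon-gamma response list, 26 of 26 tested members rose (26 adjusted over the list alone), with a median log2 fold change of 2.90 and a camera adjusted p = 6.11e-58, or adjusted p = 0.0262 with an estimated correlation. For MHC class I presentation, 19 of 19 tested members rose (19 adjusted over the list alone; median 1.44, camera adjusted p = 3.08e-45, adjusted p = 0.0262 with an estimated correlation). Tap1 changed by a log2 of 2.46. For type I interferon genes, 22 of 22 tested members rose (22 adjusted over the list alone; median 1.39, camera adjusted p = 9.24e-38, adjusted p = 0.0279 with an estimated correlation). Zbp1 changed by a log2 of 3.08. Of cytotoxic and NK cell markers, 14 of 15 tested members rose (15 adjusted over the list alone; median 1.26, camera adjusted p = 1.05e-22, adjusted p = 0.0456 with an estimated correlation). Gzma (log2 2.36) and Prf1 (2.32) moved most. Of the IL-12 and T helper 1 list, 5 of 6 tested members rose (5 adjusted over the list alone; median 0.71, camera adjusted p = 1.63e-06, adjusted p = 0.0262 with an estimated correlation). Tbx21 changed by a log2 of 1.33. Of monocyte and macrophage markers, 12 of 18 tested members rose (14 adjusted over the list alone; median 0.74, camera adjusted p = 9.23e-15, adjusted p = 0.0460 with an estimated correlation). Ly6c2 changed by a log2 of 2.37 and Plac8 by 1.98. Of chemokine and cytokine genes, 7 of 16 tested members rose (8 adjusted over the list alone; median 0.44, camera adjusted p = 4.57e-10, adjusted p = 0.0282 with an estimated correlation). Ccl8 changed by a log2 of 1.94. Of the myeloid immune suppression list, 4 of 20 tested members rose (9 adjusted over the list alone; median 0.25, camera adjusted p = 0.000375, adjusted p = 0.0460 with an estimated correlation). Il10 changed by a log2 of 0.64. Calls lost with an estimated correlation included MHC class II, of which 9 of 13 tested members rose (9 adjusted over the list alone; median 0.77, camera adjusted p = 9.47e-14, adjusted p = 0.0536 with an estimated correlation). Ciita changed by a log2 of 1.74. Of proliferation genes, 12 of 15 tested members rose (15 adjusted over the list alone; median 0.45, camera adjusted p = 1.74e-11, adjusted p = 0.111 with an estimated correlation). Of dendritic cell markers, 3 of 7 tested members rose and 1 fell (3 rising and 1 falling adjusted over the list alone; median 0.21, camera adjusted p = 0.0164, adjusted p = 0.235 with an estimated correlation).

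Downward calls in naive lungs were small. Airway epithelial markers had 0 members passing in limma (0 adjusted over the list alone, 0 on RPM and 6 lower at an unadjusted p under 0.05; median -0.25, camera adjusted p = 0.000348, adjusted p = 0.235 with an estimated correlation). Endothelial markers had 1, Ednrb (3 adjusted over the list alone; median -0.17, camera adjusted p = 0.00358, adjusted p = 0.278 with an estimated correlation). Of adipocyte and mesothelial markers, 2 of 5 tested members fell (3 adjusted over the list alone; median -0.22, camera adjusted p = 0.0171, adjusted p = 0.235 with an estimated correlation). Of fibroblast markers 0 passed (0 adjusted over the list alone, 0 on RPM and 1 at an unadjusted p under 0.05; median -0.17, camera adjusted p = 0.0253, adjusted p = 0.495 with an estimated correlation). That call was lost without naive_untreated replicate 1 (adjusted p = 0.129) or naive_GEMy replicate 4 (adjusted p = 0.122). Of B cell markers 1 passed (1 adjusted over the list alone; median -0.25, camera adjusted p = 0.00729, adjusted p = 0.381 with an estimated correlation), lost without naive_untreated replicate 4 (adjusted p = 0.0513). The erythroid and platelet list had 0 of 13 members passing in limma, also adjusted over the list alone, on RPM and at an unadjusted p under 0.05 (median -0.35, camera adjusted p = 0.0463, adjusted p = 0.634 with an estimated correlation). It lost its call without naive_untreated replicate 1 or 2 or naive_GEMy replicate 1, 2 or 3 (adjusted p = 0.0575 to 0.258), and hemoglobin transcripts took 0.10 to 0.335% of reads in naive_GEMy. The circadian clock list moved upward, and 0 of 9 members passed in limma (0 adjusted over the list alone, 3 higher at an unadjusted p under 0.05 and 2 fell on RPM; median 0.13, camera adjusted p = 0.0463, adjusted p = 0.468 with an estimated correlation). That list lost its call without naive_untreated replicate 3 or 4 or naive_GEMy replicate 3 or 4 (adjusted p = 0.0620 to 0.249). With fry the B cell (adjusted p = 0.105), erythroid (0.405), fibroblast (0.217) and circadian calls (0.214) were lost. No neutrophil marker passed in limma (0 of 17, also adjusted over the list alone, on RPM and at an unadjusted p under 0.05; median -0.048, camera adjusted p = 0.990).

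In naive lungs 730 genes changed in limma, 576 higher and 154 lower, 149 and 1 of them at least 2-fold. The split was 487 higher and 290 lower after quantile normalization, 618 and 663 after GC correction and 520 and 265 with hemoglobin as a covariate, and leaving out naive_GEMy replicate 4 gave 472 genes.

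**Figure D3:**
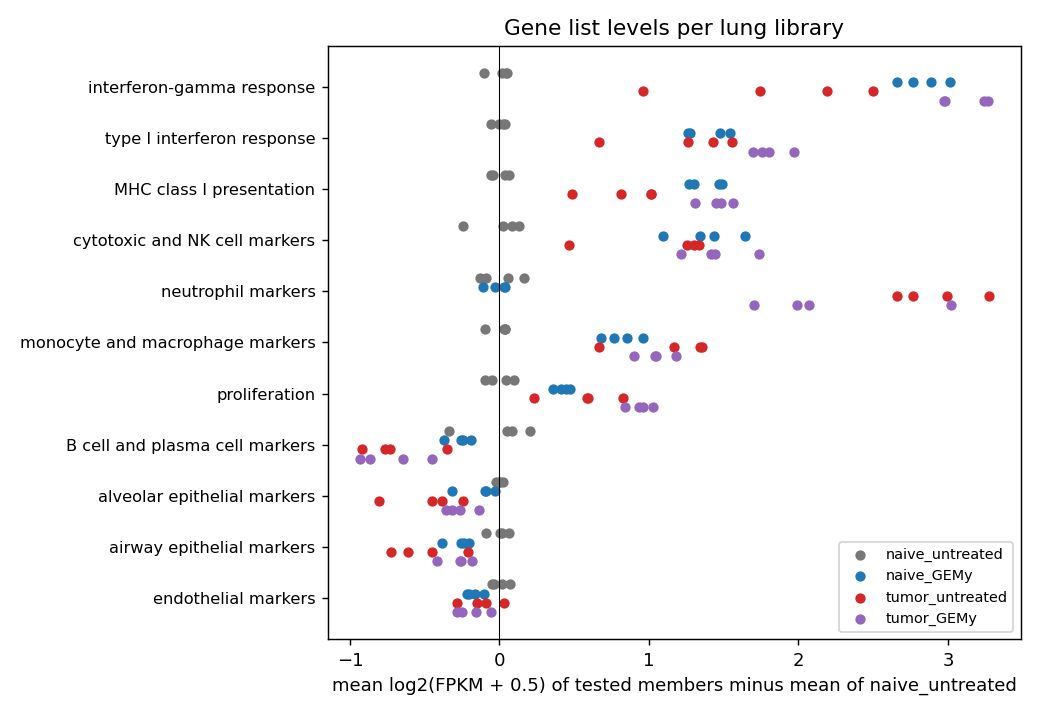
Level of 11 gene lists in each lung library, as the mean log2(FPKM + 0.5) of tested members minus the mean of naive_untreated, with 1 point per library coloured by group. Neutrophil markers are raised in both tumor groups alone, whereas the interferon-gamma response list is highest in the GEMy groups and intermediate in tumor_untreated.

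Lungs of treated tumor-bearing mice were also set against both naive groups, to ask how far they remained from a lung without a tumor. Against naive_untreated, Arg1 no longer differed detectably (log2 0.075, adjusted p = 0.777), while S100a8 (3.72, 553 ± 329.5 FPKM), S100a9 (3.67), Cxcl9 (4.20), Cd274 (3.79), Ifng (2.03) and Mki67 (1.46) were higher. Of the interferon-gamma response list, 26 of 26 tested members rose (26 adjusted over the list alone; median 3.23, camera adjusted p = 2.26e-34, adjusted p = 0.0535 with an estimated correlation). Of the neutrophil list, 17 of 17 tested members rose (17 adjusted over the list alone; median 1.86, camera adjusted p = 7.80e-19, adjusted p = 0.0559 with an estimated correlation). Proliferation genes were all higher (15 of 15, also adjusted over the list alone; median 0.87, camera adjusted p = 2.31e-16, adjusted p = 0.0559 with an estimated correlation). Of the B cell list, 8 of 10 tested members fell (9 adjusted over the list alone; median -0.77, camera adjusted p = 0.000535, adjusted p = 0.241 with an estimated correlation). Of 19 lists called, 1 held with an estimated correlation, myeloid immune suppression. In it, 14 of 20 tested members rose and 2 fell (14 rising and 3 falling adjusted over the list alone; median 0.57, camera adjusted p = 1.15e-07, adjusted p = 0.0335 with an estimated correlation). In limma 4038 genes changed, 1403 higher and 2635 lower, and median-of-ratios scaling gave 1811 higher and 1605 lower. On RPM, the log2 fold change was -0.92 (adjusted p = 0.000280) for Il12a, 1.66 (adjusted p = 1.59e-05) for Il12b and 0.43 (adjusted p = 0.0928) for Foxp3, which did not pass.

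Against naive_GEMy, which received the same cells, neutrophil genes set the tumor apart: 17 of 17 tested members rose (17 adjusted over the list alone; median 1.84, camera adjusted p = 7.34e-36, adjusted p = 0.0294 with an estimated correlation), with S100a8 at 3.77 (adjusted p = 3.86e-06) and S100a9 at 3.80. No member of the interferon-gamma response list passed in limma (0 of 26, also adjusted over the list alone, with 2 higher at an unadjusted p under 0.05 and 1 higher on RPM), although the list as a whole was higher (median 0.30, camera adjusted p = 5.81e-05, adjusted p = 0.585 with an estimated correlation), a call lost with hemoglobin as a covariate (adjusted p = 0.223) and with fry (adjusted p = 0.437). Cxcl9 (log2 0.96, adjusted p = 0.114), Cd274 (0.12, 0.804) and Arg1 (0.10, 0.748) did not pass, and Cxcl9 passed in a fit of the 8 compared libraries alone (adjusted p = 0.00607) and with array weights (adjusted p = 0.00630). Mki67 was higher (0.92, adjusted p = 0.000391), as were 12 of 15 proliferation genes (13 adjusted over the list alone; median 0.52, camera adjusted p = 8.78e-17, adjusted p = 0.0978 with an estimated correlation). Ifng was higher (0.84, adjusted p = 0.0146), a call lost with hemoglobin as a covariate (adjusted p = 0.218). Of the myeloid immune suppression list, 8 of 20 tested members rose and 1 fell (9 rising and 2 falling adjusted over the list alone; median 0.18, camera adjusted p = 2.20e-06, adjusted p = 0.0294 with an estimated correlation). Of the B cell list, 6 of 10 tested members fell (8 adjusted over the list alone; median -0.53, camera adjusted p = 0.00103, adjusted p = 0.292 with an estimated correlation). On RPM Foxp3 was higher at 0.65 (adjusted p = 0.0438), and Il12a (-0.39, adjusted p = 0.119) and Il12b (0.61, adjusted p = 0.0765) did not pass. Hemoglobin transcripts took 0.306 to 2.41% of reads in tumor_GEMy and 0.10 to 0.335% in naive_GEMy.

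Against naive_GEMy 1357 genes changed in limma, 414 higher and 943 lower. That split was 553 and 414 after median-of-ratios scaling, 527 and 658 after quantile normalization and 587 and 773 after GC correction, and with hemoglobin as a covariate 105 higher and 48 lower genes were called. Leaving out naive_GEMy replicate 1, 2 or 3 gave 641, 799 and 859 genes, and leaving out tumor_GEMy replicate 1 or 2 gave 778 and 893.

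The interaction asked whether the effect of the cells differed between tumor-bearing and naive lungs. The chemokine genes Cxcl10 (interaction log2 fold change -3.49, SE 0.55, adjusted p = 0.00288) and Cxcl9 (-3.18), the granzyme gene Gzmb (-2.49), Serpina3f (-2.41) and Tgtp1 (-2.29) had the largest negative values. Gzmb was at 15.4 FPKM in the cell product and 10.2 ± 1.48 FPKM in naive_GEMy. It was at 19.6 ± 7.82 FPKM in tumor_untreated, where no cells were given. Whether injected cells contributed to its values in treated lungs was not tested. Cxcl10 rose 4.04 with GEMy in naive lungs, and in tumor-bearing lungs it went from 23.5 ± 14.9 to 30.0 ± 10.1 FPKM (SD, n = 4; log2 0.55, adjusted p = 0.488). Cd274 (interaction -1.77, adjusted p = 0.0139) rose in both, to 26.2 ± 3.60 FPKM in naive_GEMy and 28.4 ± 3.62 FPKM in tumor_GEMy. Arg1 had an interaction of -1.15 (adjusted p = 0.0190), lost with voom (adjusted p = 0.0657). The largest positive values were those of Clca1 (log2 fold change 3.13, SE 0.81, adjusted p = 0.0345), Retnla (2.33, adjusted p = 0.00543), Tff2 (1.16), Muc5b (1.16) and Rasd1 (1.03). The Clca1 call was lost on leaving out any 1 of naive_untreated replicates 1 to 4, naive_GEMy replicates 1, 2 and 4, tumor_untreated replicates 2 to 4 or tumor_GEMy replicate 4 (adjusted p = 0.0545 to 0.0794). It was also lost with no minimum (adjusted p = 0.0562), on RPM (adjusted p = 0.0633) and with voom (adjusted p = 0.0959). The Tff2 call was lost without naive_untreated replicate 1 or 2, naive_GEMy replicate 1 or 4, tumor_untreated replicate 2 or 3 or tumor_GEMy replicate 4 (adjusted p = 0.0504 to 0.0613), and with no minimum (adjusted p = 0.0533). S100a8 (interaction -0.79, adjusted p = 0.348), S100a9 (-0.67, 0.393), Ifng (-0.10, 0.883) and Mki67 (0.051, 0.911) did not pass, nor on RPM did Il12a (0.37, adjusted p = 0.394), Il12b (-0.86, adjusted p = 0.118) and Foxp3 (0.33, adjusted p = 0.558). Ifng lay below the added 0.5 in naive_untreated (0.0444 ± 0.0136 FPKM), which understates its rise in naive lungs. Its interaction value therefore cannot show whether Ifng rose by equal folds in naive and tumor-bearing lungs.

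None of the 18 lists called for the interaction held with an estimated correlation, where the adjusted p was 0.156 to 0.452. In the interferon-gamma response list 21 of 26 tested members passed below 0 (25 adjusted over the list alone; median -1.44, camera adjusted p = 3.97e-22, adjusted p = 0.156 with an estimated correlation). For MHC class I presentation 13 of 19 tested members passed below 0 (18 adjusted over the list alone; median -0.73, camera adjusted p = 2.86e-17, adjusted p = 0.156 with an estimated correlation). For type I interferon genes 10 of 22 tested members passed below 0 (15 adjusted over the list alone; median -0.65, camera adjusted p = 1.54e-11, adjusted p = 0.221 with an estimated correlation). Among monocyte and macrophage markers 10 of 18 tested members passed below 0 (14 adjusted over the list alone; median -0.87, camera adjusted p = 3.23e-12, adjusted p = 0.156 with an estimated correlation). Among cytotoxic and NK cell markers 8 of 15 tested members passed below 0 (15 adjusted over the list alone; median -0.88, camera adjusted p = 1.70e-10, adjusted p = 0.199 with an estimated correlation). In the neutrophil list 6 of 17 tested members passed below 0 (6 adjusted over the list alone; median -0.75, camera adjusted p = 6.76e-06, adjusted p = 0.313 with an estimated correlation), a call lost with fry (adjusted p = 0.0553). Among immediate early and heat shock genes 4 of 14 tested members passed below 0 (9 adjusted over the list alone; median -0.52, camera adjusted p = 2.65e-05, adjusted p = 0.190 with an estimated correlation). Alveolar (median 0.34, camera adjusted p = 1.40e-05, adjusted p = 0.156 with an estimated correlation) and airway epithelial markers (median 0.28, camera adjusted p = 4.49e-06, adjusted p = 0.156 with an estimated correlation) had positive values, with 0 of 17 and 2 of 12 members passing (0 and 3 adjusted over the list alone). At an unadjusted p under 0.05, 5 alveolar members were higher in limma, and 0 passed on RPM. Proliferation genes had no call (0 of 15 in limma, also adjusted over the list alone, at an unadjusted p under 0.05 and on RPM; camera adjusted p = 0.879).

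The interaction passed for 644 genes in limma, 107 positive and 537 negative, and the split was 223 and 406 after quantile normalization and 484 and 559 after GC correction. Leaving out naive_untreated replicate 1 or 2 gave 384 and 407 genes, naive_GEMy replicate 1 or 4 gave 423 and 383, tumor_untreated replicate 3 gave 385, and tumor_untreated replicate 1 gave 1256.

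**Figure D4:**
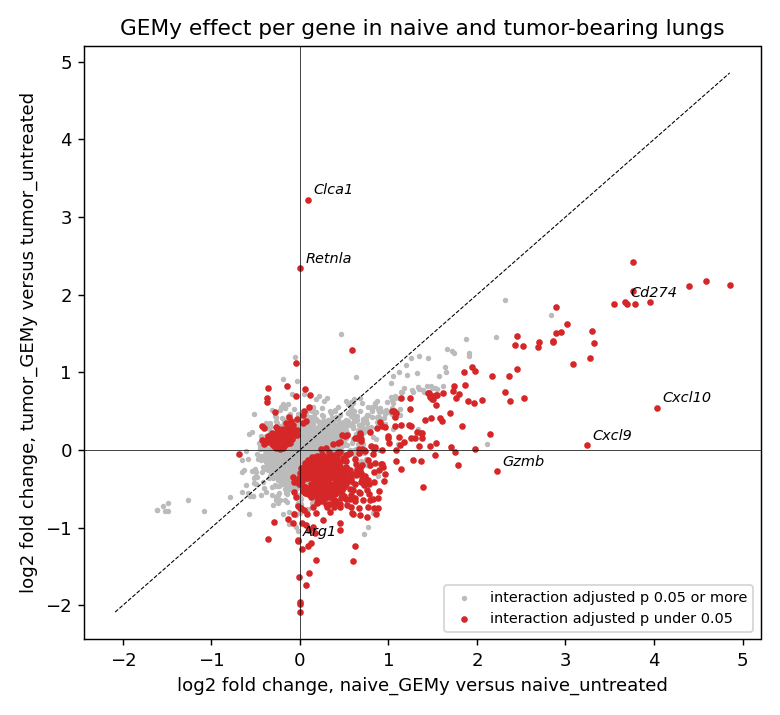
GEMy effect of each tested gene as log2 fold change in naive lungs (horizontal) and in tumor-bearing lungs (vertical), with genes past the interaction threshold in red and a dashed line of equal effects. Of the interferon-gamma response list, 21 of 26 genes pass below the line, and Clca1 and Retnla lie far above it.

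Genes raised by GEMy were shared between tumor-bearing and naive lungs: 202 were higher in both, against 17.3 if independent, and 8 were lower in both, against 5.74. In opposite directions, 39 were lower in tumor-bearing and higher in naive lungs, against 21.5, and 1 the other way, against 4.63. Across the 10284 genes, which are not independent replicates, Pearson's r of the effects was 0.40 and Spearman's rho -0.030, and r was 0.22 without tumor_untreated replicate 1. The tumor effect and the GEMy effect in naive lungs, which share the naive_untreated libraries, had r = 0.61, where simulated unchanged groups gave 0.50, and 490 genes rose in both, against 97.1 if independent. With the naive_untreated libraries split 2 and 2, so that the effects shared none, 249 to 322 rose in both over the 6 splits, against 38.4 to 59.5. The covariance of these effects was 0.0786 against 0.00567 simulated. To ask whether the cells returned genes toward the naive level, the tumor effect was compared with the GEMy effect in tumor-bearing lungs. Of genes raised by the tumor, 307 fell with GEMy (64.5 if independent) and 163 rose further (52.1), and of genes lowered by it, 62 rose (84.0) and 9 fell further (104). Shared libraries alone raise the first count, so the tumor_untreated libraries were also split 2 and 2 between the effects. Over the 6 splits 86 to 350 raised genes fell (21.4 to 44.9 if independent) and 70 to 227 rose further (20.1 to 56.1). Of genes lowered by the tumor, 19 to 59 rose (20.9 to 88.3 if independent), above that number in 1 of 6 splits. Those that fell further numbered 3 to 33 (25.8 to 69.9), above it in 0 splits. The effects share the tumor_untreated libraries, which alone gave r = -0.50 in simulated unchanged groups, and the real r was -0.25. The simulated groups held no effects, and real effects widen the spread of both effects, so these values of r cannot be compared. The same holds for r = 0.61 and the simulated 0.50 above. The covariance was -0.0237 against -0.00556 simulated. With the tumor_untreated libraries split 2 and 2 the mean r was -0.17, from -0.45 to 0.14 over the splits, so the direction was not fixed across splits.

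The injected cell product was described from its 1 library, without replicates. Ranked by FPKM per genomic span, which is low for genes with long introns, its highest transcripts included the housekeeping genes Eef1a1 (2833 FPKM), Actb (1698) and Hspa8 (1068), with the macrophage gene Lyz2 at 788. Genes at least 8 times the lung mean, 86 in number, included granule genes of immature myeloid cells: Mpo at 166 FPKM (54735 reads, 95% counting interval 164 to 167) against 0.378 ± 0.288 FPKM in lungs (SD, n = 16), Ctsg at 146, Elane at 137 and Prtn3 at 114. The platelet genes Pf4 (321) and Ppbp (251), Spp1 (291), Ifitm1 (525) and Ccr2 (132) were also among them. So were genes of the proliferation list such as Mki67, Top2a, Ccna2 and Rrm2, so results for enriched genes partly repeat that list. Il12a was at 2.22 FPKM (546 reads, 95% counting interval 2.04 to 2.41), 13.8 times the lung mean, and Il12b at 0.330 FPKM (150 reads, 95% counting interval 0.279 to 0.387), 1.85 times the lung mean. Whether reads of the IL-12 construct count for either gene is unknown. Mki67 was at 59.4 FPKM, Arg1 at 0 reads, and the lung epithelial gene Sftpc at 3 reads. In lungs, the 84 tested product-enriched genes had a median log2 fold change of 0.31 in naive_GEMy versus naive_untreated (38 rose, 0 fell) and 0.13 in tumor_GEMy versus tumor_untreated (19 rose, 6 fell). The same genes had a larger median, 0.55, in tumor_untreated versus naive_untreated (62 rose, 0 fell), where no cells were given. With enrichment of at least 4 times the lung mean (241 tested genes) the medians were 0.21 (64 rose, 0 fell), 0.020 (24 rose, 20 fell) and 0.35 (143 rose, 7 fell) in the same order. These medians exceeded those of 10000 random lists at either enrichment. The random lists were matched on mean expression alone. They carry none of the correlation between genes of a shared process, so they cannot decide whether the shifts exceed chance. Of the list of granule genes of immature myeloid cells, 0 of 11 tested members passed in limma in naive_GEMy versus naive_untreated. On RPM and at an unadjusted p under 0.05 the number was also 0.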

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

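The tests of end levels, of RNA of the injected cells, of the share of resident lung cells and of blood as a source of the lower genes were chosen after the result was seen, as were the GC and hemoglobin corrections. Of 359 checks of 4 libraries, 25 had 1 library far from the other 3, where chance gives about 17.95. Values are FPKM with the range of the other 3 libraries in parentheses. In tumor_GEMy replicate 1 the neutrophil genes were high and 1 dendritic cell gene low, with S100a8 1046 (362 to 419), Retnlg 205 (65.9 to 71.8), Ngp 127 (15.1 to 17.1), and Ccl17 7.56 (9.40 to 9.71). Elsewhere in tumor_GEMy were Ccl19 3.01 (1.67 to 1.79) in replicate 2, Tbx21 1.89 (at most 1.47) and Nptx1 0.795 (1.38 to 1.42) in replicate 3, and Ager 432 (613 to 658), Cfd 90.3 (32.3 to 36.7) and Rasd1 2.63 (3.98 to 4.22) in replicate 4. In tumor_untreated replicate 1 had Gzmb 8.16 (21.3 to 25.4) and Ifit3b 4.24 (7.74 to 8.60), replicate 2 had Nr4a1 30.1 (24.5 to 25.1), and replicate 4 had Ccl8 6.20 (4.00 to 4.22). In naive_GEMy replicate 2 had Cxcl9 3.96 (5.72 to 5.90). Replicate 3 of that group had the heat shock genes Hspa1a 25.3 (5.67 to 5.96) and Hspa1b 23.6 (4.09 to 5.14), and replicate 4 had Gbp10 9.21 (7.02 to 7.23). In naive_untreated replicate 1 had Plac8 1.86 (2.46 to 2.53), replicate 3 had Cyp1a1 2.12 (3.23 to 3.37), Ager 709 (832 to 858) and Myl7 21.5 (at least 25.6), and replicate 4 had Gbp6 1.40 (2.08 to 2.21). On the principal components, naive_GEMy replicate 4 scored -1.24 on the first (-8.77 to -7.50) and naive_untreated replicate 4 scored -6.15 on the second (-8.67 to -8.33).

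The effect of GEMy differed between tumor-bearing and naive lungs by the interaction test for 644 genes. Those picked for the interaction, with Arg1 and Cd274 from the fixed genes, had values of 3.13 for Clca1, 2.33 for Retnla, 1.16 for Tff2, 1.16 for Muc5b and 1.03 for Rasd1, and of -3.49 for Cxcl10, -3.18 for Cxcl9, -2.49 for Gzmb, -2.41 for Serpina3f, -2.29 for Tgtp1, -1.15 for Arg1 and -1.77 for Cd274. Of all 61 genes named for a GEMy comparison, 36 passed the interaction, 30 negative and 6 positive. Over all 10284 tested genes 644 passed, 537 of them negative. Most of the 61 were picked by their GEMy effect in these same libraries, so their share is no separate support. The Clca1 call was lost on leaving out any 1 of naive_untreated replicates 1 to 4, naive_GEMy replicates 1, 2 and 4, tumor_untreated replicates 2 to 4 or tumor_GEMy replicate 4 (adjusted p = 0.0545 to 0.0794). The Tff2 call was lost without naive_untreated replicate 1 or 2, naive_GEMy replicate 1 or 4, tumor_untreated replicate 2 or 3 or tumor_GEMy replicate 4 (adjusted p = 0.0504 to 0.0613).

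For each pair of groups, 1 of 35 splits of the 8 libraries, the real one, gave as many genes as the real count. That is the smallest share that 35 splits can give, and no allowance was made for the number of pairs compared. The other splits count the group difference itself as spread, which lowers their counts. Chance in the division of libraries was therefore not excluded by these splits. The real counts and the highest of the other splits were 4530 and 1133 for tumor_untreated versus naive_untreated, 692 and 461 for tumor_GEMy versus tumor_untreated, and 730 and 0 for naive_GEMy versus naive_untreated. For tumor_GEMy they were 4038 and 0 against naive_untreated and 1357 and 0 against naive_GEMy. For the interaction, 2 of 100 drawn splits, the real one included, gave as many genes as the real 644. Exchanging GEMy names also counts the GEMy effect itself as spread, so these splits cannot exclude chance for the interaction. The highest other split gave 1080. It exchanged the GEMy names of all 4 naive_GEMy libraries and of 3 of 4 tumor_GEMy libraries, so it held most of the real grouping in mirror image.

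Neutrophil genes were higher in tumor-bearing lungs. A larger amount of blood left in the lung was argued against. The median log2 fold change of the list was 2.72 with hemoglobin as a covariate and 2.86 without it. Hemoglobin follows red cells, so more neutrophils within the same amount of blood could not be tested. A single library was argued against too, as the lowest median without 1 tumor_untreated library was 2.79. A larger number or a changed state of neutrophils in the lung or in its blood may explain the rise. Bulk RNA cannot divide these. The immediate early and heat shock list, which handling can raise, was also higher in tumor_untreated than in any other lung library (0.635 to 0.896 against at most 0.452). It was at -0.0756 to 0.321 in tumor_GEMy and -0.0285 to 0.452 in naive_GEMy. The neutrophil list was at 1.70 to 3.02 in tumor_GEMy and at most 0.0349 in naive_GEMy. Handling that raises the immediate early list was thereby argued against as the sole source in tumor-bearing lungs. Other differences in handling stay open.

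The interferon-gamma response list rose less with GEMy in tumor-bearing than in naive lungs, by an interaction median of -1.44. A lower end level after treatment was argued against, since the list was 0.30 higher in tumor_GEMy than in naive_GEMy at the median. RNA of the injected cells in the state of the cell product was argued against. Only 4 of 26 members were higher in that product than in the mean of naive_GEMy lungs. Genes that these cells raised after injection could not be tested from that library. One untreated tumor-bearing library was argued against as the sole source, since the median interaction was at most -1.24 without any 1 of them. With similar end levels, the smaller rise lay in a higher level before treatment. All 26 members were higher in tumor_untreated than in naive_untreated, by 1.76 at the median, and the mean level of the list was 0.961 to 2.50 in the tumor_untreated libraries against at most 0.0489 in naive_untreated. A response already raised by the tumor may explain this, as a hypothesis from the same data. What the numbers in the tumor descriptions stand for was not tested, since in naive samples the descriptions count the replicates.

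More genes were lower than higher in tumor_untreated against naive_untreated, with 38.3% of changed genes higher. Scaling to a fixed total was not decided. The share was 51.6% after median-of-ratios scaling and 34.9% after quantile normalization. By the rule fixed beforehand, a share as high as the first in either scaling counted for scaling as the cause. That rule was met but not applied. Median-of-ratios scaling centres the log ratios (median of all genes -0.048 before and 0.0021 after), so its share decides nothing. GC content was not decided. The share was 32.6% after correction, but the correction also recentres each library. The median of all genes went from -0.048 to -0.077, which by itself makes more genes lower. Blood left in the lung was not decided, since the share was 46.8% (1456 of 3109) with hemoglobin as a covariate but 42.0% without tumor_untreated replicate 4, which held most hemoglobin. An equal fall of all resident lung cells as the whole cause was argued against, since it would lower their markers alike. A loss of unequal size was not tested, nor was the spread of list medians over their members. The medians of the alveolar, airway, endothelial and fibroblast lists were -0.50, -0.44, -0.19 and -0.40, a range of 0.304 that stayed between 0.272 and 0.328 without any 1 library. A change of particular cell types remains open, and the tumor itself, which the design names, was not separated from it.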

How the results depend on the processing

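RPM, voom, the GC correction, the hemoglobin covariate and the overlaps of effects with a split untreated group were chosen after the data were seen, and the other alternatives before. Counts of changed genes stayed within 1.5 times under both pseudocounts, both minimums, median-of-ratios scaling, quantile normalization, plain moderation, RPM and voom. With the replicate number as a block the counts were 4768 for tumor_untreated versus naive_untreated, 827 for tumor_GEMy versus tumor_untreated, 829 for naive_GEMy versus naive_untreated, 4341 for tumor_GEMy versus naive_untreated, 1587 for tumor_GEMy versus naive_GEMy and 799 for the interaction. The correlation of same-numbered residual profiles was -0.31 to 0.20, 0.089 to 0.256 and -0.24 to 0.33 in the comparisons of tumor, of GEMy in tumor-bearing and of GEMy in naive lungs. In 0 of the 3 did all 4 pairs exceed 0.1, so the numbers were not taken to pair the samples. For GEMy in tumor-bearing lungs that stays uncertain, as 3 of 4 pairs exceeded 0.1 and 2 correlated best with their own number. The sample descriptions also carry a running number, in which each replicate number is a consecutive run with a library of each group. Counts with the block were higher than without it in every comparison, so an effect of that order was not excluded.

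Array weights gave 2358 genes for tumor_GEMy versus tumor_untreated, 2051 for naive_GEMy versus naive_untreated, 2733 for tumor_GEMy versus naive_GEMy and 1881 for the interaction. The GC correction gave 1281 for naive_GEMy versus naive_untreated and 1043 for the interaction. Hemoglobin as a covariate gave 153 for tumor_GEMy versus naive_GEMy. Fitting only the groups compared gave 210 for tumor_GEMy versus tumor_untreated and 1188 for naive_GEMy versus naive_untreated. In these cases the cause was not tested. A 2-fold minimum, which by construction lowers every count, left 346, 68, 150, 321, 69 and 152 in the order given above for the block.

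Leaving out 1 library gave 3500 to 5118 genes for tumor_untreated versus naive_untreated and 3319 to 3694 for tumor_GEMy versus naive_untreated. The range was 452 (without tumor_GEMy replicate 2) to 913 for tumor_GEMy versus tumor_untreated and 472 (without naive_GEMy replicate 4) to 658 for naive_GEMy versus naive_untreated. It was 641 to 1265 for tumor_GEMy versus naive_GEMy, with 641, 799 and 859 without naive_GEMy replicates 1, 2 and 3, and 778 and 893 without tumor_GEMy replicates 1 and 2. For the interaction it was 383 to 1256, with 384 and 407 without naive_untreated replicates 1 and 2, 423 and 383 without naive_GEMy replicates 1 and 4, and 1256 and 385 without tumor_untreated replicates 1 and 3. The correlation of GEMy effects ranged from 0.22 (without tumor_untreated replicate 1) to 0.51 (without tumor_untreated replicate 4). Fewer samples lower the power by construction, and where counts rose the cause was not tested.

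The erythroid and platelet list changed direction with hemoglobin as a covariate, at adjusted p = 0.170 in naive_GEMy versus naive_untreated and 0.873 in tumor_GEMy versus naive_GEMy, since the covariate is itself a member of the list. In naive_GEMy versus naive_untreated the fibroblast list lost its call after GC correction (adjusted p = 0.0774), the adipocyte list after GC correction (0.0626) and the B cell list with hemoglobin (0.0674). On RPM the adipocyte (0.0548) and circadian lists lost it there (0.365). The circadian list also lost it with a pseudocount of 0.1 (0.0511), after median-of-ratios scaling (0.0532) and with hemoglobin (0.0591), and the erythroid list with a pseudocount of 1 (0.0574), after quantile normalization (0.112) and after GC correction (0.266). In tumor_untreated versus naive_untreated the erythroid list lost it with hemoglobin (0.968), and the adipocyte list gained one after median-of-ratios scaling (0.0394). On RPM the alveolar macrophage list lost its call in tumor_GEMy versus tumor_untreated (0.0546), and the regulatory T cell list, with 13 members tested there, gained one in every other comparison, from adjusted p = 5.49e-06 in tumor_GEMy versus naive_untreated to 0.0131 in the interaction. Apart from leaving out libraries, list results were the same in 1440 cases, lost a call in 149, gained one in 29 and reversed in 2. Of these, the estimated correlation lost 95 and gained 0, and fry lost 22 and gained 7. Of 161 named gene results, 145 kept their call and direction without any 1 library and 16 did not.

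Lung libraries had at least 27566840 assigned reads, and genes under 0.5 FPKM were not tested on that scale. In simulated data made from these libraries 94 to 95% of planted 2-fold changes and 80 to 83% of 1.5-fold changes were called. Those simulated genes varied independently, with 1 spread per gene for all groups.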

Other observations

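No test in this part was planned, and the genes here were chosen after their values were seen. Clca1 was 2.7, 5.03, 30.6 and 19.7 FPKM and Retnla 71.1, 83.0, 241 and 180.2 FPKM in tumor_GEMy replicates 1 to 4. In the same libraries Muc5ac was at 0.169, 0.245, 0.877 and 0.750 FPKM and Chil4 at 0.0273, 0.0632, 0.873 and 0.944 FPKM. Adipoq, a gene of fat cells, was at 0.877, 0.869, 0.871 and 3.64 FPKM in the same libraries, where Cfd was highest in replicate 4.

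Hemoglobin transcripts took 0.734, 1.51, 0.330 and 0.190% of reads in naive_untreated replicates 1 to 4, 0.244, 0.121, 0.10 and 0.335% in naive_GEMy, 1.28, 1.54, 0.553 and 5.41% in tumor_untreated and 2.08, 2.41, 0.306 and 0.484% in tumor_GEMy. The clock gene Per1, which stress hormones also induce, was at 4.16, 3.00, 4.59 and 3.76 FPKM in naive_untreated and 20.2, 12.0, 13.2 and 13.3 FPKM in tumor_untreated, while the circadian list as a whole had no call in that comparison.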
